A study of Mus musculus with 12 samples.

How the data were processed

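RNA sequencing of mouse kidney was deposited as 1 table of 43346 genes, 22032 of them protein-coding, with 2 columns of values for each of 12 samples, 6 sham and 6 HP-AKI at day 1. Per the labels, RNA was extracted with Trizol and Qiagen columns and libraries were made with the TruSeq RNA v2 kit and read on an Illumina HiSeq instrument. The submitters' processing notes name TopHat2 2.1.0, featureCounts, edgeR and the GRCm38 build, without giving their roles, settings or filters. The deposited counts are raw whole numbers per gene made by the authors with 1 column per sample, and no normalization was found in them. The deposited RPKM values were made by the authors per kilobase of the listed gene length and per sample total, and that total lay at 2.98 to 3.47 times the sum of the counts. The RPKM values served only for this check and no test used them. All 37 genes of the mitochondrial genome are listed at 0 in every library, so the fixed list of 10 mitochondrial-genome genes had 0 tested members. No library was left out of the main tests, and no library pair was near-identical.

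Each sample was placed in the group its label gives. The groups share no sample numbers, so no pairing could be made, and no batch is given in the sources used here. Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) after filterByExpr with the group and TMM factors, with a quasi-likelihood F-test, two-sided, and Benjamini-Hochberg adjustment over the 17470 genes kept. The SE of a log2 fold change was its size divided by the square root of F. The common biological coefficient of variation was 0.178 and the median SE of a log2 fold change 0.141. CPM values were scaled with the TMM factors. Gene lists were tested against all other genes with camera on log2 CPM (prior count 2) at its preset correlation of 0.01, with adjustment over the 30 lists of at least 4 tested members. Beside this, camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without reference to other genes, were run. Within HP-AKI, 4 relations between list means were tested over all 720 orders with adjustment over the 4. Values in HP-AKI of genes without a sham count are given against 3 counts over the group. Ratios of genes with 1 to 3 sham counts carry exact binomial counting intervals at 95% confidence. The GC content and overlaps of genes were taken from the GENCODE vM21 annotation of GRCm38. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.

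Before the data were examined, the tests, 31 gene lists, the processing alternatives and the rule for named genes were fixed. The 415 list entries all matched a gene, 5 of them by identifier under an older symbol, and no gene stood in 2 lists. The lists covered tubular injury markers, heme and iron handling, NRF2 target genes, cyclin-dependent kinase inhibitors, p53 target genes, secreted inflammatory and senescence-associated factors, cell cycle and proliferation, immediate early genes, ATF4 and endoplasmic reticulum stress, heat shock proteins, acute phase proteins, hypoxia response and glycolysis, proximal tubule transport, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, gluconeogenesis and fructose metabolism, cholesterol synthesis, kidney hormone and vitamin D genes, loop of Henle and distal convoluted tubule, collecting duct, podocytes, endothelial cells, fibroblasts, pericytes and matrix, monocytes and macrophages, neutrophils, lymphocytes, red blood cells, neighbouring fat, adrenal gland and skeletal muscle, circadian clock, sex-linked genes and the mitochondrial genome. The rule always named Hmox1, Havcr1, Lcn2, Cdkn1a, Cdkn2a and Kl. It added the 6 largest rises and 6 largest falls among genes past an adjusted p of 0.05 with a mean of at least 5 CPM and no overlap of the groups, skipping predicted genes, and from each list the 2 called members with the largest change and the member with the highest mean CPM. This gave 93 genes. Some of these and some other list members are not reported here. Adgre1, Cx3cr1, Ltf, Dbp, Mki67, Top2a, Lrp2, Slc12a1 and Hbb-bs, and list members named only to spell out a small count, a dependence on 1 library or a further example, were chosen after their values were seen.

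The same steps were tested on simulated data of the same size with planted changes. There 67, 66 and 64 of 17303 tested genes had true log2 changes of 0.5, 1 and 2. Of these, edgeR called 35.8%, 86.4% and 100% in the right direction. Unchanged genes made up 6.45% of its calls, against 22.2% for DESeq2 1.42.0 and 5.88% for limma-voom. In the real data 72.8% of tested genes passed, so these rates need not hold there. Camera and fry found the planted list and called 0 of 40 unchanged lists. The simulated genes were drawn independently, so this does not show how often camera calls unchanged lists of correlated genes. Alternatives planned were DESeq2-type (RLE), upper-quartile and library-size-only scaling, no filter on low counts, a filter of 1 CPM in 6 samples, DESeq2, limma-voom, robust dispersion, leaving out the 10 most abundant and the mitochondrial genes, a test against a 1.5-fold change, the other list tests, z-scores for the relations, and leaving out each of the 12 libraries in turn. Offsets for GC content in 20 bins and leaving out sham 1, sham 2 and HP-AKI 8 together were added after the data were seen.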

Results

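Messenger RNA of mouse kidney was measured in 12 libraries, 6 from sham mice (samples 1 to 6) and 6 from mice with HP-AKI (samples 7, 8, 9, 11, 12 and 13), all at day 1. AKI stands for acute kidney injury. In this field HP-AKI is used for heme protein-induced AKI, a model in which heme proteins such as myoglobin or hemoglobin reach the kidney in excess, although the labels do not spell the letters out. The sham libraries held 35201197 to 41951129 counts assigned to genes and the HP-AKI libraries 31624522 to 40630917. At least 1 count was present for 22757 ± 156 (SD, n = 6) genes in sham and 23499.5 ± 232 (SD, n = 6) genes in HP-AKI, out of 43346 genes listed. A gene without a count in any sham library could at this depth still have been present at up to 0.0137 counts-per-million (CPM), the level of 3 counts over the group. Nothing in the labels says that the samples are separate animals, so the p-values measure only the spread between these libraries, which may be technical. Intervals and floors cover counting error only.

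The comparison of HP-AKI with sham asked which kidney genes differed at day 1. Hmox1, Havcr1, Lcn2 and Cdkn1a were among the genes that rose, and Kl, Slc2a2, Cubn and Egf among those that fell. Of 17470 genes tested, 12720 passed an adjusted p of 0.05 (edgeR quasi-likelihood F-test, Benjamini-Hochberg), 6579 higher and 6141 lower in HP-AKI. Of these, 5787 changed at least 2-fold, 2805 higher and 2982 lower. By fitted fold change, 485 genes were at least 8-fold higher and 248 at least 8-fold lower. All 6 HP-AKI values lay outside the range of the 6 sham values in 9158 tested genes (52.4%), where chance gives 0.216%, and 9155 of these had passed the test. The first principal component held 81.3% of the variance in log2 CPM and separated the groups. The second held 7.85% and spread the libraries of both groups, with HP-AKI 8, sham 2 and sham 1 at its lower end and HP-AKI 13 at its upper end, and without the lower 3 libraries 13430 genes passed. Scaling by library size alone moved the median log2 fold change of all tested genes from 0.04 to 0.16, so small changes are relative to the TMM scaling.

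**Figure D1:**
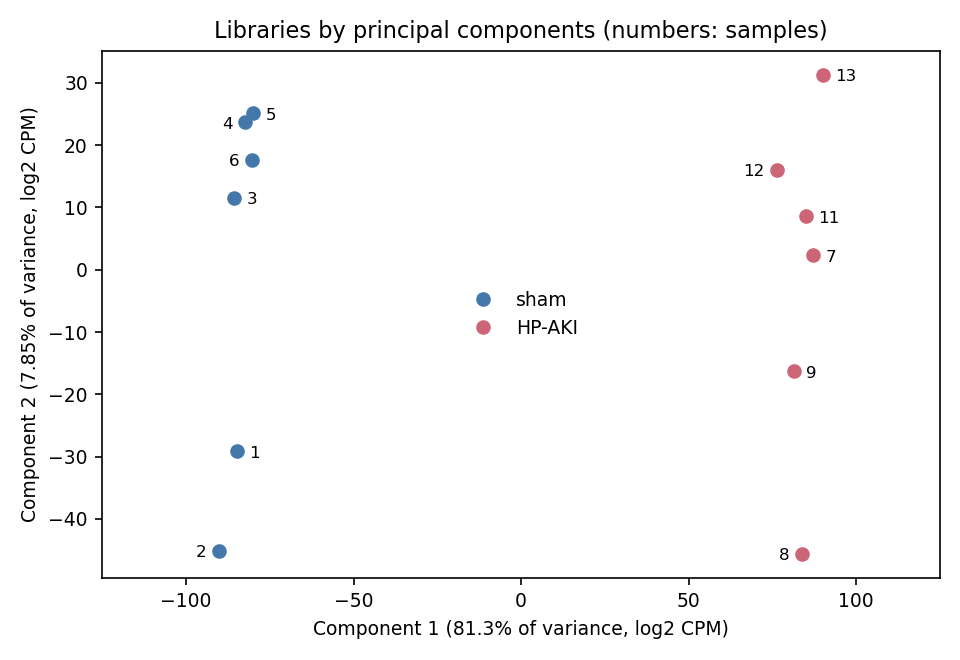
Each point is a library, placed by its scores on the first component (horizontal axis, 81.3% of the variance in log2 CPM) and the second component (vertical axis, 7.85%), blue for sham and red for HP-AKI, with the sample number beside it. The groups lie at opposite ends of the first component, and sham 1, sham 2, HP-AKI 8 and HP-AKI 13 have scores of -29.17, -45.13, -45.63 and 31.32 on the second.

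Of the 6 genes followed whatever their result, 4 rose, 1 fell and 1 was too rare to test. Hmox1, heme oxygenase 1, the inducible enzyme that breaks down heme, rose from 22.3 ± 5.46 (SD, n = 6) to 2675 ± 545 (SD, n = 6) CPM, a log2 fold change of 6.91 ± 0.21 (SE). Havcr1, kidney injury molecule 1, rose from 4.90 ± 0.873 to 803 ± 189 CPM, a log2 fold change of 7.36 ± 0.19. Lcn2, which encodes the siderophore-binding protein NGAL, rose from 2.16 ± 0.638 to 2078 ± 327 CPM, a 959-fold difference. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 5.44 ± 0.676 to 504 ± 65.9 CPM, a 92.5-fold difference. Kl, the anti-ageing hormone and FGF23 co-receptor klotho, fell from 1055 ± 70.1 to 129 ± 13.3 CPM, an 8.20-fold difference. In each of these 5 genes all 6 HP-AKI values lay beyond the sham values, and the adjusted p ran from 3.32e-14 for Cdkn1a to 1.57e-12 for Hmox1. Cdkn2a, which encodes the senescence marker p16, had 0 counts in sham and 3 counts in HP-AKI, all in HP-AKI 11, and was not tested. Under GRCm38 these protein-coding genes are Hmox1 (ENSMUSG00000005413, chromosome 8, 75093591 to 75100596), Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) and Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722). Kl (ENSMUSG00000058488) lies on chromosome 5 from 150952607 to 150993809, and Cdkn2a (ENSMUSG00000044303) on chromosome 4 from 89274471 to 89294653.

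**Figure D2:**
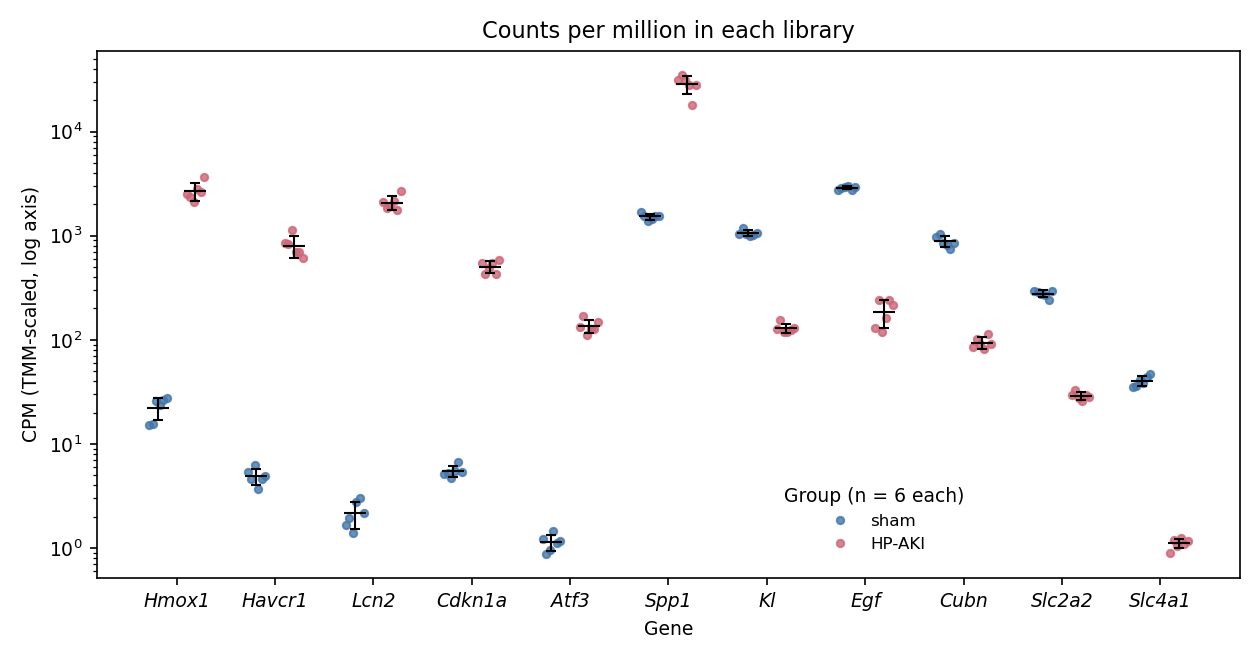
Expression of 11 named genes (horizontal axis) in CPM on a log axis (vertical axis, TMM-scaled), with 1 point per library, blue for sham and red for HP-AKI, and black bars for the mean ± SD of 6 libraries. The groups do not overlap in any of these genes, with Spp1 rising from 1527 to 28643 CPM and Slc4a1 falling from 40.2 to 1.11 CPM.

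Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest rises were those of Fosl1, Sprr2f, Mmp10, Krt20, Sult1e1 and Lcn2. Fosl1, a subunit of the AP-1 transcription factor, had no count in sham and 77.0 ± 12.1 (SD, n = 6) CPM in HP-AKI, at least 5617-fold higher against a floor of 3 counts over the sham group. Sprr2f, a small proline-rich protein of stressed epithelia, and Mmp10, the matrix metalloproteinase stromelysin 2, also had no count in sham. They were at least 1464-fold and at least 1137-fold higher in HP-AKI, at 20.1 ± 9.69 and 15.6 ± 6.46 CPM. Krt20, an epithelial keratin, rose from 0.623 ± 0.352 to 824 ± 102 CPM, a log2 fold change of 10.34 ± 0.28. Sult1e1, estrogen sulfotransferase, rose from 0.0193 to 21.2 CPM, a log2 fold change of 9.93 ± 0.81. This became 9.27 without HP-AKI 12 and 10.54 without sham 1, and the sham level rested on 4 counts. Adjusted p-values of these genes ran from 6.40e-14 for Lcn2 to 2.98e-07 for Sprr2f. Sprr2f belongs to a family of near-identical genes and Fosl1 overlaps Ccdc85b on the opposite strand. The strand setting of the counting is not given and the library kit does not mark the strand, so the counts of such overlapping or near-identical genes are uncertain.

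The largest falls by the same rule were those of Slitrk6, Slc4a1, Perm1, St8sia1, Bcl11b and Hsd3b2. Slc4a1, the chloride-bicarbonate exchanger of red cells and of acid-secreting intercalated cells, fell from 40.2 ± 4.52 (SD, n = 6) to 1.11 ± 0.121 (SD, n = 6) CPM, a 36.1-fold difference. Slitrk6, a neuronal membrane protein, fell from 11.6 ± 3.16 to 0.308 ± 0.152 CPM, and Perm1, a muscle regulator of oxidative metabolism, from 10.9 ± 1.37 to 0.436 ± 0.212 CPM. St8sia1, a sialyltransferase of ganglioside synthesis, fell from 240 ± 30.3 to 9.79 ± 2.19 CPM, a log2 fold change of -4.61 ± 0.15. Bcl11b, a zinc-finger transcription factor, fell by 4.53 on the log2 scale, and Hsd3b2, a steroid dehydrogenase with near-identical relatives, fell by 4.51. Their adjusted p-values ran from 6.40e-14 for Slc4a1 to 8.03e-10 for Bcl11b.

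All 14 tubular injury markers rose (14 adjusted over the list alone), with a median log2 fold change of 3.49. Spp1, the secreted matrix protein osteopontin, rose from 1527 ± 99.8 (SD, n = 6) to 28643 ± 5815 (SD, n = 6) CPM and took 0.146% of all counts in sham and 2.99% in HP-AKI. Timp1, an inhibitor of matrix metalloproteinases, rose by 6.63 ± 0.30 (SE) on the log2 scale, and Sox9, a transcription factor of regenerating tubules, by 5.29 ± 0.16. The smallest rise was that of Vcam1 at 0.62, which no longer passed without HP-AKI 7 (0.50) or HP-AKI 8 (0.42). Of 17 tested genes of heme and iron handling, 12 rose and 4 fell (the same counts adjusted over the list alone). Beside Hmox1, Fth1, the ferritin heavy chain that stores iron, rose from 2271 ± 163 to 5771 ± 279 CPM, and Hp, the hemoglobin-binding protein haptoglobin, from 1.67 ± 1.15 to 13.2 ± 6.95 CPM. Blvra, which turns biliverdin into bilirubin, Tfrc, the transferrin receptor, Slc46a1, a heme and folate importer, and Fech, the last enzyme of heme synthesis, fell by 0.71, 1.25, 1.58 and 0.59 on the log2 scale. Slc40a1, the iron exporter ferroportin, did not pass (-0.18) but did in 2 of 24 alternatives, 1 of them without HP-AKI 8 (-0.32), and Hamp, hepcidin, was too rare to test. Hpx, the heme-binding hemopexin, counted among the rises at 0.61 but did not pass without sham 1, 2, 5 or 6 or without HP-AKI 7, 8, 11, 12 or 13 (0.47 to 0.64). Against all other genes (camera), the injury list stood higher at an adjusted p of 1.29e-07 and the heme and iron list at 0.0471 (adjusted p = 0.166 with an estimated correlation). The heme and iron call also ended with library size only (adjusted p 0.0784), with the filter of 1 CPM in 6 samples (0.0586), without sham 1 (0.0540) and without HP-AKI 12 (0.0560), within a range of 0.0364 to 0.0784 over its 16 alternatives at the preset correlation.

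Camera put 20 of 30 lists past an adjusted p of 0.05, 11 higher and 9 lower. The tubular injury, NRF2, p53 and immediate early gene lists were the 4 that also passed with an estimated correlation between genes, each at an adjusted p of 0.0380. For all 20 lists this estimated correlation gave the highest adjusted p of any alternative.

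Of 17 tested NRF2 target genes, the antioxidant program switched on by oxidative stress, 16 rose and 1 fell (the same adjusted over the list alone), with a median of 1.76. Slc7a11, the cystine importer that feeds glutathione synthesis, rose from 0.430 ± 0.298 (SD, n = 6) to 229 ± 43.7 (SD, n = 6) CPM, and Srxn1, sulfiredoxin, from 77.7 ± 1.74 to 2435 ± 405 CPM. Txnrd1, thioredoxin reductase, rose by 3.45 ± 0.08 (SE) on the log2 scale. Me1, malic enzyme, was the member that fell (-1.13 ± 0.08). Of 15 p53 target genes, 13 rose and 2 fell (the same adjusted over the list alone), with a median of 1.43. Gdf15, a stress cytokine, rose by 5.89 ± 0.35, the kinase Plk3 by 4.55 ± 0.26 and the p53 ubiquitin ligase Mdm2 by 1.15 ± 0.08. Ccng1, cyclin G1, and Polk, a DNA polymerase that bypasses lesions, fell by 0.39 and 0.52. Adjusted p-values of the lists were 3.48e-06 for NRF2 and 2.29e-04 for p53.

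Among 6 tested cyclin-dependent kinase inhibitors, Cdkn1a and Cdkn2b (p15) rose, the latter from 1.43 ± 0.553 (SD, n = 6) to 3.75 ± 1.14 (SD, n = 6) CPM. Cdkn1b (p27) and Cdkn2c (p18) fell by 0.43 and 1.05 on the log2 scale, and Cdkn1c (p57, 0.01) and Cdkn2d (p19, 0.28) did not pass. The counts were the same adjusted over the list alone, and the list did not differ from other genes (adjusted p 0.705). Of 21 genes of cell cycle and proliferation, 7 rose, 6 fell and 8 did not pass (7 and 6 adjusted over the list alone), with a list adjusted p of 0.656. Pcna, the DNA polymerase clamp, rose from 38.5 ± 5.57 to 83.9 ± 7.42 CPM and Ccne1, cyclin E1, which drives entry into DNA synthesis, from 0.739 ± 0.207 to 1.73 ± 0.235 CPM, with the replication genes Mcm2, Mcm3, Mcm5 and Rrm2 and the mitotic kinase Plk1 also higher. Mki67, a marker of cycling cells, fell from 13.8 ± 7.12 to 7.55 ± 2.24 CPM and Top2a, topoisomerase II alpha, from 10.1 ± 5.04 to 5.40 ± 1.92 CPM, both with overlapping groups. Mki67 no longer passed without sham 1 (-0.72) or sham 2 (-0.66), nor Top2a without sham 2 (-0.71). Sham 1 and sham 2 held the highest sham values of Mki67 (20.9 and 23.3 CPM). Both lay at the lower end of the second component and of a GC-related axis described below. The 24 alternatives included GC offsets and a fit without sham 1, sham 2 and HP-AKI 8. Over them Mki67 ran from -1.04 to -0.51 and passed in 19, and Top2a from -1.07 to -0.62 and passed in 21. How much of these falls goes with the GC-related axis was not separated. Tyms, thymidylate synthase, fell by 1.10 ± 0.09 (SE). Cenpf, a centromere protein, counted among the falls at -0.69 but did not pass without sham 1, 2, 3 or 6 or without HP-AKI 7, 9, 11 or 13 (-0.54 to -0.72), while Aurka (0.44) and Mcm6 (0.21) did not pass. Of 24 alternatives, Aurka passed in 2, 1 of them without HP-AKI 8 (0.57), and Mcm6 in 5, with library size only (0.33), limma-voom or GC offsets or without sham 2 or 6 (0.26 and 0.25).

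All 12 immediate early genes, the first transcripts induced by growth and stress signals, rose (12 adjusted over the list alone), with a median of 3.67 and a list adjusted p of 6.59e-07. Atf3, a stress-induced transcription factor, rose from 1.13 ± 0.205 (SD, n = 6) to 136 ± 20.3 (SD, n = 6) CPM. Egr1 rose from 9.999 ± 4.78 to 216 ± 34.1 CPM, and Fosb, an AP-1 subunit, by 5.88 ± 0.38 (SE) on the log2 scale (6.51 without sham 6). Of 14 genes of the ATF4 and endoplasmic reticulum stress list, 12 rose (12 adjusted over the list alone), with a median of 2.15. Trib3, a pseudokinase induced by ATF4, rose by 5.34 ± 0.21, Chac1, which degrades glutathione, by 4.34 ± 0.26, and Hspa5, the chaperone BiP, from 742 ± 141 to 3315 ± 346 CPM. Herpud1 (-0.02) and Sdf2l1 (-0.11) did not pass. That list stood higher at an adjusted p of 5.48e-05 (adjusted p = 0.0750 with an estimated correlation). Of 11 heat shock proteins, 9 rose and 1 fell (the same adjusted over the list alone), with a median of 2.39. The inducible chaperones Hspa1a and Hspa1b, whose sequences are nearly identical, rose by 6.46 ± 0.24 and 5.68 ± 0.29, and the constitutive Hspa8 from 1855 ± 238 to 3998 ± 223 CPM. Hspd1, the mitochondrial chaperone, fell by 0.48, and Serpinh1 (0.23) did not pass but did in 2 of 24 alternatives, without sham 5 (0.27) and with library size only (0.34). The heat shock list stood higher at an adjusted p of 2.29e-04 (adjusted p = 0.153 with an estimated correlation).

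Of 11 tested acute phase genes, 10 rose and 1 fell (the same adjusted over the list alone), with a median of 3.30. Saa3, a serum amyloid, rose from 0.0304 CPM, 7 counts over the sham group, to 3.47 ± 1.92 (SD, n = 6) CPM. Serpina3n, a protease inhibitor, rose from 0.911 ± 0.283 to 73.5 ± 9.65 CPM. The fibrinogen chains Fga, Fgb and Fgg rose by 3.30, 4.11 and 3.52 on the log2 scale. Cfb, complement factor B, was the member that fell, from 430 ± 60.7 to 170 ± 26.8 CPM. Saa1 rose by 2.86 (3.78 without sham 3), and C3, complement component 3, by 0.37 but not past the threshold without HP-AKI 7 (0.32) or HP-AKI 13 (0.31). The list stood higher at an adjusted p of 8.67e-04 (adjusted p = 0.0571 with an estimated correlation). Of 18 tested secreted inflammatory and senescence-associated factors, 16 rose (17 adjusted over the list alone), with a median of 2.65. Il6, the interleukin that induces acute phase genes, rose by 6.50 ± 0.46 (SE), and Igfbp3, a binding protein of insulin-like growth factors, from 289 ± 16.6 to 453 ± 107 CPM. Areg, the EGF receptor ligand amphiregulin, had 2 counts in sham and 263 in HP-AKI, a ratio of 130.4 with a counting interval of 35.7 to 1083. Tnf (0.68) did not pass, nor did Ccl7 (1.02), which passed in 5 of 23 alternatives, with library size only (1.14) or without sham 5, sham 6, HP-AKI 9 or HP-AKI 13 (1.15 to 1.35). This list stood higher at an adjusted p of 2.00e-06 (adjusted p = 0.0963 with an estimated correlation).

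Of 25 genes of proximal tubule transport, 24 fell (24 adjusted over the list alone), with a median of -1.87. Slc2a2, the glucose transporter GLUT2, fell from 278 ± 20.8 (SD, n = 6) to 28.9 ± 2.43 (SD, n = 6) CPM. Cubn and Lrp2, the endocytic receptors cubilin and megalin that reclaim filtered proteins, fell from 883 ± 109 to 94.0 ± 11.98 CPM and from 3740.2 ± 343 to 497 ± 38.3 CPM. Slc34a1, the sodium-phosphate cotransporter NaPi-IIa, fell from 3377 ± 797 to 1097 ± 343 CPM. Slc9a3, the sodium-proton exchanger NHE3, did not pass (-0.16 ± 0.12, SE) but did in 1 of 24 alternatives, without sham 1, sham 2 and HP-AKI 8. The list stood lower at an adjusted p of 6.04e-10 (adjusted p = 0.0552 with an estimated correlation).

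Of 18 genes of fatty acid oxidation, 16 fell (16 adjusted over the list alone), with a median of -0.99. Acsm2, an acyl-CoA synthetase of the proximal tubule, fell from 7052 ± 586 (SD, n = 6) to 1844 ± 211 (SD, n = 6) CPM. Cpt1a (-0.06), which admits fatty acids to mitochondria, and Slc25a20 (-0.02), the carnitine carrier, did not pass. Of 16 nuclear genes of oxidative phosphorylation, 15 fell (15 adjusted over the list alone), with a median of -0.81. Ndufs1 of complex I fell by 1.601 ± 0.10 (SE) on the log2 scale, Sdha of complex II by 1.23 ± 0.07 and Atp5b of the ATP synthase by 0.84 ± 0.07, while Cox4i1 did not pass (-0.10) but did in 1 of 24 alternatives, with GC offsets (-0.36). Of 8 genes of gluconeogenesis and fructose metabolism, 7 fell (7 adjusted over the list alone), with a median of -1.51. G6pc, glucose-6-phosphatase, fell from 673 ± 74.9 to 124.5 ± 47.0 CPM and Fbp1 from 857 ± 73.1 to 221 ± 44.7 CPM, and Tkfc did not pass (-0.08). Adjusted p-values were 1.42e-04 for fatty acid oxidation (adjusted p = 0.272 with an estimated correlation), 6.69e-05 for oxidative phosphorylation (adjusted p = 0.166 with an estimated correlation) and 0.00514 for gluconeogenesis (adjusted p = 0.346 with an estimated correlation).

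Of 15 genes of cholesterol synthesis, 8 fell and 2 rose (the same adjusted over the list alone), with a median of -0.69. Hmgcs1, the cytosolic HMG-CoA synthase, fell from 914 ± 120.4 (SD, n = 6) to 200.2 ± 33.3 (SD, n = 6) CPM and Mvd, mevalonate diphosphate decarboxylase, from 21.2 ± 9.30 to 4.98 ± 1.59 CPM. Msmo1, a sterol oxidase, rose by 0.79 on the log2 scale. Insig1 did not pass (-0.15) except without sham 4 (-0.25), nor did Fdft1 (-0.09), Fdps (-0.18) and Sc5d (-0.07). The list stood lower at an adjusted p of 0.0266 (adjusted p = 0.374 with an estimated correlation). Of 9 kidney hormone and vitamin D genes, 7 fell and 1 rose (the same adjusted over the list alone), with a median of -1.36. Beside Kl, Cyp24a1, which inactivates vitamin D, fell from 86.4 ± 35.9 to 20.8 ± 16.4 CPM with overlapping groups, Cyp27b1, which activates it, by 1.36 ± 0.19 (SE), and the vitamin D receptor Vdr by 1.51 ± 0.07. Ren1, renin, rose by 0.72 ± 0.17, and Epo, erythropoietin, did not pass (0.11 ± 0.47). This list stood lower at an adjusted p of 0.0171 (adjusted p = 0.313 with an estimated correlation).

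Of 11 genes of the loop of Henle and distal convoluted tubule, 7 fell and 1 rose (the same adjusted over the list alone), with a median of -2.44. Egf, epidermal growth factor, fell from 2877 ± 99.1 (SD, n = 6) to 184 ± 54.9 (SD, n = 6) CPM, Slc12a1, the furosemide-sensitive cotransporter NKCC2, from 2238 ± 169.5 to 308 ± 60.4 CPM, and Pvalb, the calcium-binding parvalbumin of the distal convoluted tubule, by 3.85 ± 0.14 (SE) on the log2 scale. Umod, uromodulin of the thick ascending limb, was at 4153 ± 407 CPM in sham and 4950.2 ± 744 CPM in HP-AKI. Its rise of 0.25 passed at an adjusted p of 0.0492 but not without sham 1, 2, 3, 4 or 6 or without HP-AKI 7, 8, 11 or 13 (0.18 to 0.26). Cldn16 (0.04) and Trpm6 (-0.06) did not pass. The list stood lower at an adjusted p of 0.00444 (adjusted p = 0.120 with an estimated correlation). Of 13 collecting duct genes, 8 fell (8 adjusted over the list alone), with a median of -0.48. Avpr2, the vasopressin receptor, fell from 16.6 ± 3.26 to 3.58 ± 0.715 CPM, and Atp6v1b1, a proton pump subunit of intercalated cells, from 115 ± 15.04 to 25.5 ± 7.08 CPM. Another subunit, Atp6v1g3, did not pass (82.1 ± 12.8 and 80.0 ± 11.7 CPM), nor did the water channel Aqp2 (0.17), Scnn1b (0.13), Fxyd4 (-0.12) and Foxi1 (-0.12). The collecting duct list stood lower at an adjusted p of 0.0293 (adjusted p = 0.0987 with an estimated correlation).

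**Figure D3:**
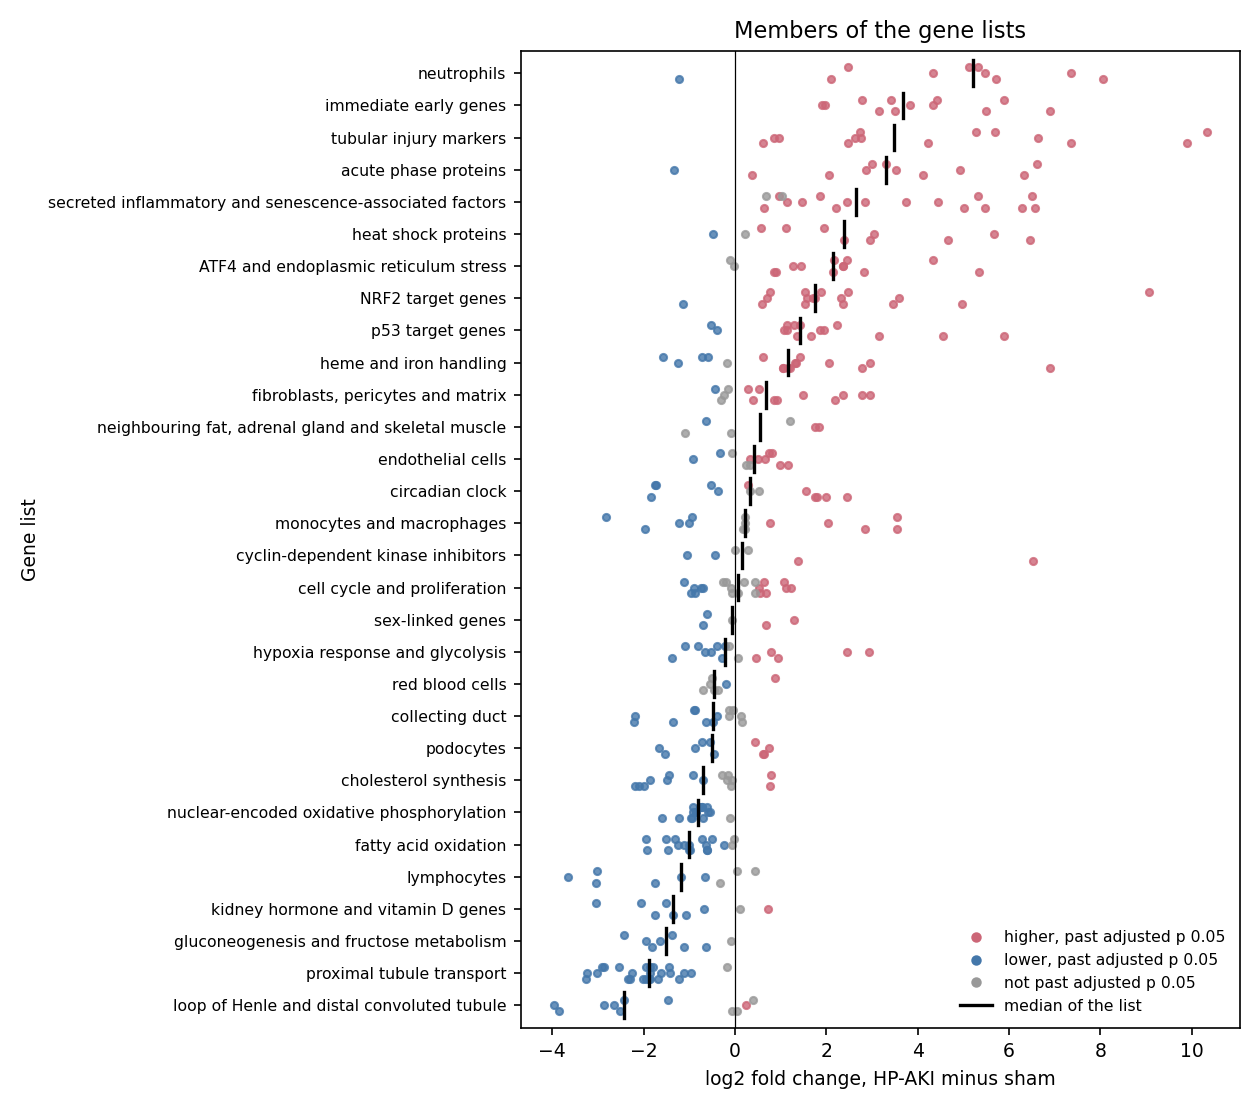
Each point is a tested member of a gene list (vertical axis), placed by its log2 fold change, HP-AKI minus sham (horizontal axis), red if higher, blue if lower and grey if not past an adjusted p of 0.05, with a black bar at the median of the list. Medians run from -2.44 for the loop of Henle and distal convoluted tubule to 5.22 for neutrophils.

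Of 10 podocyte genes, 6 fell and 4 rose (the same adjusted over the list alone; list adjusted p 0.541). Npr3, a natriuretic peptide receptor, fell by 1.66 ± 0.12 (SE) and Clic3 by 1.54 ± 0.29 on the log2 scale, while Podxl, podocalyxin, Synpo and Wt1 rose by 0.45 to 0.74. Of 12 endothelial genes, 7 rose and 2 fell (the same adjusted over the list alone; list adjusted p 0.215). Flt1, a VEGF receptor, rose from 98.0 ± 6.02 (SD, n = 6) to 220 ± 29.1 (SD, n = 6) CPM and Cdh5, VE-cadherin, from 31.7 ± 2.39 to 62.6 ± 17.7 CPM, whereas Ehd3 and the angiopoietin receptor Tek fell by 0.33 and 0.92. Tie1 (-0.06) did not pass but did in 1 of 24 alternatives, with GC offsets. Emcn (0.24) and Plvap (0.32) did not pass. Of 24 alternatives, Emcn passed in 3, without HP-AKI 12 (0.32), with library size only (0.37) and with GC offsets (0.27), and Plvap in 2, without HP-AKI 8 (0.39) and with library size only (0.44). Eng, among the rises at 0.67, did not pass without HP-AKI 13 (0.46). Of 14 genes of fibroblasts, pericytes and matrix, 10 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 0.69. Lox, which cross-links collagen, rose from 8.56 ± 1.89 to 66.7 ± 21.0 CPM, Tnc, tenascin C, from 19.8 ± 4.12 to 136 ± 28.6 CPM and Ctgf, a connective tissue growth factor, from 108 ± 13.8 to 557 ± 171 CPM. Lum, lumican, fell by 0.43, and the collagen genes Col1a1 (-0.23) and Col1a2 (-0.15) did not pass but each did in 1 of 24 alternatives, with GC offsets (-0.51 and -0.31). Fibronectin Fn1 did not pass (-0.30) but did in 12 of 24 alternatives, among them those without sham 1, 2 or 6 or without HP-AKI 7 or 8 (-0.32 to -0.43). Dcn, decorin, counted among the rises at 0.29 but did not pass without sham 3, 4, 5 or 6 or without HP-AKI 7, 8, 9, 11 or 13 (0.16 to 0.30). The fibroblast list stood higher at an adjusted p of 0.0297 (adjusted p = 0.290 with an estimated correlation) and did not pass with GC offsets (0.0552) or without sham 1, sham 2 and HP-AKI 8 (0.0514), within a range of 0.0197 to 0.0552 over its 16 alternatives at the preset correlation.

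Leukocyte markers went apart. Of 10 tested neutrophil genes, 9 rose and 1 fell (the same adjusted over the list alone), with a median of 5.22. Ly6g, Ngp and Camp were too rare to test. S100a9, a calcium-binding protein abundant in neutrophils, rose from 0.646 ± 0.202 (SD, n = 6) to 26.1 ± 23.6 (SD, n = 6) CPM, a log2 fold change of 5.32 that became 4.68 without HP-AKI 8, and its partner S100a8 rose by 5.47 (4.78 without HP-AKI 8). Mmp8, neutrophil collagenase, had only 5 counts in sham and 921 in HP-AKI. It rose by 7.36 on the log2 scale (6.59 without HP-AKI 8 and 8.19 without sham 6). Trem1, an activating receptor, had 2 counts in sham, both in sham 5, and 729 in HP-AKI, a ratio of 362 with a counting interval of 99.7 to 2991. Ltf, lactoferrin, fell from 0.676 ± 0.184 to 0.291 ± 0.123 CPM. The neutrophil list stood higher at an adjusted p of 0.00149 (adjusted p = 0.313 with an estimated correlation). Of 9 tested lymphocyte genes, 6 fell (6 adjusted over the list alone), with a median of -1.18. Cd8a, the co-receptor of cytotoxic T cells, fell from 2.62 ± 0.494 to 0.207 ± 0.185 CPM and Cd3g, a chain of the T cell receptor complex, from 0.814 ± 0.277 to 0.0957 ± 0.0609 CPM. The B cell gene Cd79a (0.05) did not pass, nor did Cd79b (-0.33) and Lck (0.44). Cd79b passed in 3 of 24 alternatives, among them without sham 2 (-0.45), and Lck in 5 of 24, among them without sham 4, sham 5 or HP-AKI 8 (0.49 to 0.55). The lymphocyte list stood lower at an adjusted p of 0.0471 (adjusted p = 0.180 with an estimated correlation) and did not pass without sham 5 (0.0664) or with GC offsets (0.0736), within a range of 0.0114 to 0.0736 over its 15 alternatives at the preset correlation. These are rare transcripts, with 1 of 13 neutrophil and 3 of 12 lymphocyte genes at a sham mean of at least 1 CPM.

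Of 14 genes of monocytes and macrophages, 5 rose and 5 fell (the same adjusted over the list alone; list adjusted p 0.720). Cd14, a co-receptor for lipopolysaccharide, rose from 3.35 ± 0.872 (SD, n = 6) to 39.5 ± 13.2 (SD, n = 6) CPM and Cd68, a lysosomal protein of macrophages, from 2.82 ± 0.360 to 33.0 ± 4.52 CPM, with Itgam, Ly6c2 and Msr1 also higher. Adgre1 (F4/80) and Cx3cr1, the fractalkine receptor, both markers of resident macrophages, fell from 9.65 ± 1.36 to 2.46 ± 0.607 CPM and from 6.12 ± 0.519 to 0.858 ± 0.462 CPM, with Csf1r, Lyz2 and Ccr2 also lower. The complement genes C1qa, C1qb and C1qc (0.17 to 0.22) did not pass, nor did Mrc1 (0.23), which passed in 3 of 24 alternatives, without sham 2 (0.32), with library size only (0.35) and with GC offsets (0.29). Of 7 red blood cell genes, Epb42 rose by 0.88 ± 0.18 (SE) and Epb41, a membrane skeleton gene also expressed in other tissues, fell by 0.20 (Epb42 alone adjusted over the list alone; list adjusted p 0.998). Epb41 did not pass without sham 1, 3, 4 or 6 or without HP-AKI 9 (-0.18 to -0.22). The 5 that did not pass were Hba-a1 (-0.46), Hba-a2 (-0.53), Hbb-bs (-0.51), Hbb-bt (-0.70) and Alas2 (-0.38). Hbb-bs, an adult beta globin, was at 159 ± 176 CPM in sham, with 514 CPM in sham 5, and at 112 ± 44.3 CPM in HP-AKI.

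Within the 6 HP-AKI libraries, none of 4 relations between list means passed an exact two-sided permutation test. The mean log2 CPM of the injury markers against that of proximal tubule transport gave a Pearson r of -0.699 (exact p = 0.132, adjusted 0.193) and a Spearman rho of -0.486 (exact p = 0.356, adjusted 0.658). Against cell cycle genes r was -0.685 (exact p = 0.138, adjusted 0.193) and rho -0.257 (exact p = 0.658, adjusted 0.658). Against genes of heme and iron handling r was -0.670 (exact p = 0.144, adjusted 0.193) and rho -0.771 (exact p = 0.103, adjusted 0.411). Against monocyte and macrophage genes r was -0.00469 (exact p = 0.994, adjusted 0.994) and rho 0.257 (exact p = 0.658, adjusted 0.658). HP-AKI 12 and HP-AKI 8 lay farthest from the median of the injury markers. Without them r became -0.548, -0.429, -0.477 and 0.817 in the same order. For Spearman's rho, 6 samples allow no exact p below 0.00278.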

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

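The tests of gene length and of cortex against medulla were chosen after the result was seen. The test of GC content was set before its own result, but the axis it concerns had been found in the data. Dixon's test was applied to each group of 6 libraries. It picks out a single library when the gap to its nearest neighbour is too large a share of the group's range. Chance alone does this in about 1 in 20 groups of normally distributed values, which CPM values need not be. Where only 1 library of a group holds counts, it is always picked out, as for Cdkn2a in HP-AKI and Trem1 in sham. A library was picked out in 22 of the 270 groups examined (8.15%).

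Of these values, 5 were in HP-AKI 12. Slc7a11, the cystine importer, was at 143 CPM there and at 227 to 265 CPM in the other HP-AKI libraries. Hspa1a, the inducible chaperone, was at 237 CPM against 378 to 438 CPM, and the mean log2 CPM of the heat shock list at 8.39 against 8.76 to 8.85. Sult1e1, estrogen sulfotransferase, was at 59.5 CPM against 9.57 to 25.9 CPM, and Cyp24a1, which inactivates vitamin D, at 53.03 CPM against 7.19 to 20.4 CPM.

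In HP-AKI 8, the neutrophil gene Mmp8 was at 13.1 CPM against 1.43 to 4.12 CPM and S100a9 at 71.9 CPM against 7.84 to 25.8 CPM in the other HP-AKI libraries. Kl in this library was at 154 CPM against 118 to 130 CPM (129.9), and the Y-linked helicase Ddx3y at 268 CPM against 189 to 214 CPM. Its mean log2 CPM of sex-linked genes was 5.07 against 4.77 to 4.85, and its ratio of RPKM total to count total 3.47 against 3.06 to 3.17.

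The remaining values were scattered over libraries. In HP-AKI 13, Trib3 was at 19.9 CPM against 10.3 to 13.9 CPM, Ucp1, a brown fat gene, at 28.2 CPM against 0.234 to 8.14 CPM, and the mean log2 CPM of the hypoxia and glycolysis list at 6.31 against 6.05 to 6.11. Cdkn2a had its only 3 counts in HP-AKI 11, 0.0692 CPM against 0 elsewhere. In sham 2, Kl was at 1191 CPM against 999.9 to 1065 CPM and Npr3 at 51.7 CPM against 30.8 to 37.4 CPM. In sham 5, Cdkn1a was at 6.73 CPM against 4.75 to 5.45 CPM, Hbb-bs at 514 CPM against 57.2 to 137 CPM, and Trem1 had its only sham counts (0.0537 CPM). G6pc was at 531 CPM in sham 4 against 659 to 735 CPM, and Ucp1 at 9.62 CPM in sham 6 against 0.182 to 2.94 CPM.

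Libraries of both groups spread along 1 axis that held 41.9% of the variance within groups, with sham 2, HP-AKI 8 and sham 1 at its lower end (-46.1, -44.8 and -29.8) and HP-AKI 13, sham 5 and sham 4 at its upper end (32.4, 24.8 and 23.1). The loading of genes on this axis rose with the GC content of their transcripts (Spearman rho 0.759 across genes, which are not independent replicates), and expression relative to the group fell by 0.41, 0.38 and 0.28 log2 for each 10 percentage points of GC in the lower 3 libraries and rose by 0.29, 0.23 and 0.21 in the upper 3, so a GC bias between libraries is a candidate explanation. A length bias is argued against by a rho of -0.127 with gene length, and another share of cortex to medulla by a mean shift of proximal tubule against collecting duct genes of -0.04567 ± 0.07197 (SE) log2 in the lower 3 libraries, while the upper ones were not tested for it. With GC offsets 13708 genes passed in place of 12720. Sham 1, sham 2 and HP-AKI 8 also had the highest ratios of RPKM total to count total of their groups (3.26, 3.21 and 3.47). The other sham libraries lay at 2.98 to 3.05 and the other HP-AKI libraries at 3.06 to 3.17. Whether this ratio goes with GC content was not tested. What made GC content act differently between libraries stays open, since no batch, RNA quality value or date is given in the sources used here.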

How the results depend on the processing

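The GC offsets and the fit without sham 1, sham 2 and HP-AKI 8 were chosen after the data were seen, and the other alternatives were planned. The count of 12720 genes ranged from 11163 with the filter of 1 CPM in 6 samples to 14633 with no filter over 23 alternatives, and from 12412 to 12961 when 1 library was left out. GC offsets gave 13708 and leaving out the 3 libraries 13430. In each of these fits at least 11131 of the 12720 genes passed again in the same direction. The share of calls that were higher in HP-AKI, 51.7%, ranged from 49.0% with upper-quartile factors to 58.0% with library size only. The 5787 genes changed at least 2-fold ranged from 4607 to 8100 over 24 alternatives with the same 2 filters at the ends, and from 5902 to 6037 when 1 library was left out. Of the 101 tested named genes, 91 stayed on the same side of the threshold in every alternative, and none that had passed changed direction, while Atp6v1g3, Ucp1 and Hbb-bs, which had not passed, took either sign. The other 10 lost the call in at least 1: Umod in 15 of 23 alternatives (adjusted p 0.00887 to 1), Aldoa in 12 of 24 (0.00263 to 0.747), Epb41 in 9 of 24 (0.00446 to 1), Mki67 in 5 of 24 (0.00431 to 0.157) and Top2a in 3 of 24 (0.0042 to 0.139), and Ccng1, Ddx3y, Igfbp3, Podxl and Uty only in the test against a 1.5-fold change, which asks for a larger effect. The count of lists past the threshold, 20, was 4 with an estimated correlation, and the cause was not tested. For the p53 and collecting duct lists the estimated correlation, -0.0063 and -0.0156, lay below the preset 0.01. Their adjusted p (camera) still rose, from 2.29e-04 to 0.0380 and from 0.0293 to 0.0987. The count was 25 with fry and 18 or 19 with GC offsets, the stricter filter, library size only or without the 3 libraries. It was 19 or 20 when 1 library was left out. With the preset correlation, 17 of the 20 called lists stayed past the threshold in every alternative, and the heme and iron, fibroblast and lymphocyte lists did not. The lymphocyte list could not be tested with the stricter filter, which left too few members. The number of relations past the threshold stayed 0 with z-scores and when any HP-AKI library was left out. Depth limited what could be said of genes near the floor, such as Cdkn2a with 3 counts in all and the sham level of Fosl1, Sprr2f and Mmp10.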

Other observations

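The tests of remaining blood, of a common leukocyte change and of the harvest hour were chosen after the result was seen. Those of GC content and of the splits were set before their own results. The GC offsets and the leukocyte and clock patterns they were applied to came after the data were seen. Circadian clock genes changed in both directions. Of 13, 6 rose and 5 fell (7 and 5 adjusted over the list alone, which adds Nr1d1; list adjusted p 0.705, median 0.33). Per1, a clock repressor that also responds to stress hormones, rose from 18.5 ± 5.84 (SD, n = 6) to 101.3 ± 33.5 (SD, n = 6) CPM, and Arntl (BMAL1), the core activator, from 5.10 ± 1.54 to 20.4 ± 2.05 CPM, with Npas2, Cry1 and Cry2 also higher. Clock counted among the rises at 0.28 but did not pass without sham 3, 4, 5 or 6 or without HP-AKI 7, 8, 9, 11 or 12 (0.22 to 0.28). The output regulators Dbp and Tef fell from 66.8 ± 17.8 to 20.02 ± 3.28 CPM and from 542 ± 75.7 to 153 ± 13.6 CPM, and Per3, Per2 and Nr1d2 by 1.76, 0.37 and 0.53 on the log2 scale. Ciart (0.33) did not pass, nor did Nr1d1 (0.53), which passed in 7 of 24 alternatives, among them those without sham 4, HP-AKI 8 or HP-AKI 9 (0.58 to 0.70).

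Genes of hypoxia and glycolysis went both ways. Of 15, 5 rose and 8 fell (the same adjusted over the list alone), and Hk1 (0.07) and Eno1 (-0.13) did not pass, although Eno1 did in 2 of 24 alternatives, with GC offsets and without sham 1, sham 2 and HP-AKI 8. Hk2, the inducible hexokinase, rose from 1.34 ± 0.353 (SD, n = 6) to 10.4 ± 3.03 (SD, n = 6) CPM and the glucose transporter Slc2a1 (GLUT1) from 21.2 ± 5.19 to 115 ± 17.0 CPM, with Pfkp and Pkm also higher. Vegfa, the vascular growth factor, and Car9, carbonic anhydrase 9, both hypoxia targets, fell by 1.10 and 1.37 on the log2 scale. The list mean was 0.15, its median -0.21 and its test toward lower at an adjusted p of 0.720, while fry pointed higher at 0.991. Aldoa, counted among the rises at 0.46, did not pass without sham 1, 2 or 3 or without HP-AKI 7, 9, 11, 12 or 13 (0.34 to 0.48), and Ankrd37, counted among the falls at -0.67, not without sham 1, 2, 3 or 5 or without HP-AKI 7, 11 or 12 (-0.52 to -0.70). Of 6 tested genes of neighbouring fat, adrenal gland and muscle, Cidec, a lipid droplet gene, rose from 1.40 ± 1.13 to 4.76 ± 2.16 CPM, with overlapping groups, and Star, which delivers cholesterol to steroid synthesis, from 1.74 ± 0.309 to 6.22 ± 0.994 CPM (the same count adjusted over the list alone; list adjusted p 0.720 toward higher, 0.0372 with fry). Mylpf fell by 0.64 but not without sham 4, sham 5, HP-AKI 7 or HP-AKI 9 (-0.53 to -0.60), and Plin1 (-0.09), Ucp1 (1.20 ± 1.03, SE) and Adipoq (-1.09) did not pass, the last except without sham 2 (-1.35). Of 5 sex-linked genes, Xist and Ddx3y rose and Kdm5d and Uty fell (the same count adjusted over the list alone), with a mean of 0.12, a median of -0.07 and a test toward lower at 0.919. The groups overlapped for Xist and Uty. Xist was at 0.239 ± 0.129 CPM in sham and 0.599 ± 0.140 CPM in HP-AKI, against 130.1 ± 28.8 and 208 ± 30.9 CPM of Ddx3y, and Eif2s3y did not pass (-0.07).

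Of the tested genes, 9 of 10 neutrophil genes rose, while 6 of 9 lymphocyte genes fell and 5 of 14 monocyte and macrophage genes rose and 5 fell, Adgre1 and Cx3cr1 among the falls but not C1qa, C1qb, C1qc and Mrc1 (0.17 to 0.23). More blood left in the HP-AKI kidneys was taken as a globin rise of at least 1 log2, a mark set after the result was seen. A rise of that size is argued against by the median log2 fold change of the 4 globin genes, -0.52. The upper bound for the highest of them was 0.49. Without sham 5, whose globins were high, the median was 0.31 and the bound 0.93, so a smaller rise in blood stays open. GC bias is argued against by all 26 called leukocyte genes staying past the threshold in the same direction with GC offsets. The lymphocyte list itself did not pass with them (camera, adjusted p 0.0736). The steepest slope of a library within its group was -0.41 log2 per 10 percentage points of GC. This test therefore bears mainly on the smaller changes. The medians of the lymphocyte and neutrophil lists, -1.18 and 5.22, only restate the pattern, so a common change in the share of all leukocytes beside other changes was not tested by them and stays open. A changed mix of leukocytes, with more neutrophils and fewer of some lymphocytes, may remain, as may changed expression within these cells or, for S100a8, S100a9 and Trem1, expression by other cells, which bulk counts cannot separate.

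For the clock genes, GC bias is argued against, since all 11 called clock genes stayed past the threshold in the same direction with GC offsets. As for the leukocyte genes, this bears mainly on the smaller changes. Another hour of harvest in the HP-AKI mice and an effect of the injury on the clock cannot be told apart: of the 6 genes Dbp, Tef, Per3, Nr1d1, Nr1d2 and Ciart, 4 had negative fold changes, and the hour is not given in the sources used here.

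The count of 12720 genes in the real grouping was reached by 1 of 100 splits of the 12 libraries into groups of 6, the real one itself, out of 462 possible splits. The highest other split gave 4447 genes, which argues against a random grouping of these 12 libraries as the source of this count. Splits that mix the groups carry the group difference in their spread, which favours the real grouping. Chance differences between animals were not covered, since the labels do not say that the libraries are separate animals.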
